A study of Homo sapiens with 6 samples.

How the data were processed

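The data are RNA-seq profiles of the H460 lung cancer line, 3 libraries of the parental cells and 3 of cells made resistant to cisplatin. Per the labels' protocols, total RNA was extracted with Trizol, mRNA was enriched on oligo(dT) beads and fragmented, and cDNA was made with random primers. The labels mention no marking of strand, so reads of overlapping and antisense genes may not be separable. The submitters' processing notes name the genome build hg38 and DESeq2, without a version, and the aligner, the counting tool and the annotation are not given in the sources used here. Groups were taken from the sample titles, and each of the 6 value columns matched 1 sample by name.

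The authors deposited TPM values, per the file headers, for 20013 genes in each library. The TPM of these genes summed to 93.1 ± 0.178% of the full TPM total in the parental libraries and to 91.3 ± 0.269% in the resistant libraries (SD, n = 3), so they are part of a larger gene set. The authors also deposited a comparison table of 16745 genes, which per the file headers holds a mean normalized count (a signal per gene over the libraries), a log2 fold change with its standard error, a p-value and an adjusted p-value. The log2 fold changes that the authors deposited are of resistant over parental cells, checked against the TPM ratio over 8778 genes with a mean normalized count of at least 200 (correlation 0.999994 across genes). They lie 0.18 above the TPM log2 ratios, a constant shift between the scalings. An adjusted p is empty for 1299 genes in the authors' table.

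TPM keeps no depth, but the low values of a gene step by 1 read. Multiples of these steps were scaled by the authors' deposited mean normalized count to recover whole reads per gene and library. Of 55879 values of genes with a mean normalized count under 500, 99.99% came within 0.05 of a whole number, and 94.8% of all values did. The recovered totals ran from 13587837 to 17337715 reads in the parental and from 15734731 to 20379629 in the resistant libraries. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom of 2.37 to 4.74 over genes, so none was treated as a library deposited more than once. This does not show that they came from separate cultures or RNA preparations, and p-values measure only the spread between these libraries.

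The design set before the data were examined assumed raw counts and named a test for TPM if none were given. Since the files hold TPM, that test was used: limma 3.58.1 (R 4.3.3) with an intensity trend on log2(TPM + 1), for the 12251 genes with a mean TPM of at least 1, with Benjamini-Hochberg adjustment and a threshold of 0.05. Adjusted p values are from this fit unless another test is named. Errors of log2 fold changes are limma's moderated standard errors, and those of TPM are SDs over 3 libraries. The test was tested on data simulated for this comparison with 12250 genes, where it recovered 62.0% of genes changed 1.25-fold, 82.0% at 1.5-fold, 98.0% at 2-fold and 100.0% at 4-fold, and called 10 of 12051 unchanged genes. Few genes were changed in the simulation (50, 50, 49 and 50 at these folds), in both directions alike, with 1 dispersion of 0.001 for all genes. In the real comparison 73.2% of genes were called and the median gene lay at -0.17, so the simulated rates may not hold there. The 39 gene lists were fixed before the data were examined, and the 36 with at least 3 tested members were tested with limma's camera (preset correlation 0.01), with an estimated correlation and with fry.

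Genes named in the text follow a rule set before the data were examined. It takes OTUD1, RAD23B and XPC, the 12 largest rises and 12 largest falls with an adjusted p under 0.05, a mean TPM of at least 5 and no overlap between the groups, up to 4 members of each list with the smallest adjusted p, and genes of the cisplatin response fixed by name, of which SLC31A1, ATP7A, ATP7B, ABCC2, ERCC1 and CDKN1A are reported. Some genes that the rule takes are not reported here. Chance gives no overlap between 3 and 3 libraries for 10% of genes. Genes outside the rule are said to be chosen after their values were seen.

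The alternatives set beforehand were a pseudocount of 0.1, no filter on low values, the replicate number as a block, leaving out each library in turn and, for gene lists, an estimated correlation and fry. Those added after seeing the data were median-of-ratios scaling of the TPM (called rescaling in the text), upper-quartile scaling, a minimum mean of 50 recovered reads, limma-voom on the recovered reads and limma's treat against a 1.5-fold change. Gene positions, lengths of the longest transcript and GC content came from GENCODE release 29 on GRCh38, with a position for 12244 of the tested genes and length and GC content for 12227. The trend of log2 fold change on GC content, length and mean expression was removed with a spline regression (statsmodels 0.14.6), and it took up 0.0396 of the variance. Tables were handled in Python 3.11.15 with pandas 2.3.3 and scipy 1.17.1. Of the genes in the TPM table, 2671 were at 0 in every library and were left out of all tests.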

Results

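RNA was measured in H460, an established human large cell lung cancer line, and in a derivative of it made resistant to cisplatin (CDDP), a platinum drug that crosslinks DNA. The series holds 6 poly(A)-selected libraries, 3 of the parental line and 3 of the resistant line, with a TPM value for each of 20013 genes per library. The reads recovered from these values came to 17337715, 13587837 and 14432226 in the parental libraries and to 15734731, 20379629 and 18419127 in the resistant libraries. Across genes, log2 TPM + 1 of libraries from 1 group correlated at 0.994 to 0.995 and those of different groups at 0.912 to 0.915, with genes not being independent replicates. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these samples. The design sets 1 comparison, resistant against parental cells, to look for mechanisms of cisplatin resistance, and the series title names OTUD1, RAD23B and XPC.

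The resistant line differed from its parent across most expressed genes. Among the lists that passed camera with a preset correlation, p53 targets, type I interferon response genes and YAP/TEAD targets were lower and mRNAs of ribosomal proteins, G2/M genes and cholesterol synthesis genes were higher (6 of 36 lists, and 0 with an estimated correlation). Of 12251 genes tested with limma, 3156 were higher and 5813 were lower in the resistant libraries at an adjusted p under 0.05. At least 2-fold, 701 were higher and 1063 lower. The median gene lay at -0.17 on the log2 scale, and with median-of-ratios scaling, which placed it at -0.01, the split was 4338 higher and 4375 lower, with 964 and 776 at least 2-fold. Values relative to the median gene or after this rescaling are given where the difference matters. Log2 fold changes are of TPM + 1 and understate the change of genes with low values.

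All 3 genes named in the title had lower mRNA levels in the resistant line (adjusted over the list alone, 3 of 3 as well, and the list was taken from the study itself and is not independent evidence), and as a list they did not pass camera (adjusted p = 0.119). XPC, which recognises DNA damage in nucleotide excision repair (chromosome 3, 14145147 to 14178783, GRCh38), fell the most, from 56.2 ± 2.86 to 19.1 ± 0.333 TPM (SD, n = 3), a log2 fold change of -1.51 ± 0.0579 (SE) with an adjusted p of 2.9e-09 in limma. OTUD1, a deubiquitinase of the OTU family (chromosome 10, 23439458 to 23442390), fell from 23.1 ± 0.223 to 13.5 ± 0.800 TPM (-0.74 ± 0.0674, adjusted p = 2.5e-06). RAD23B, the partner of XPC in damage recognition (chromosome 9, 107283137 to 107332194), fell from 186 ± 4.41 to 141 ± 3.13 TPM (-0.40 ± 0.0406, adjusted p = 5.4e-06). After median-of-ratios scaling the values were -1.33, -0.57 and -0.22 for XPC, OTUD1 and RAD23B, and the authors' deposited table gives -1.37, -0.60 and -0.22. In a test against a 1.5-fold change, XPC passed, whereas OTUD1 (adjusted p = 0.099) and RAD23B (adjusted p = 1) did not. XPC also belongs to the list of p53 targets. The tested genes of its chromosome lay lower as a whole, with a median of -0.33 after rescaling. With the trend on GC content, length and expression removed instead, the median was -0.28. Protein levels were not analysed here. Of the 14 tested members of the OTU family, 3 were higher and 9 lower (4 and 8 after rescaling), among them TNFAIP3 (-0.47, and -0.28 after rescaling) and OTUD6B (-0.93), and the list did not pass camera (adjusted p = 0.514).

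**Figure D1:**
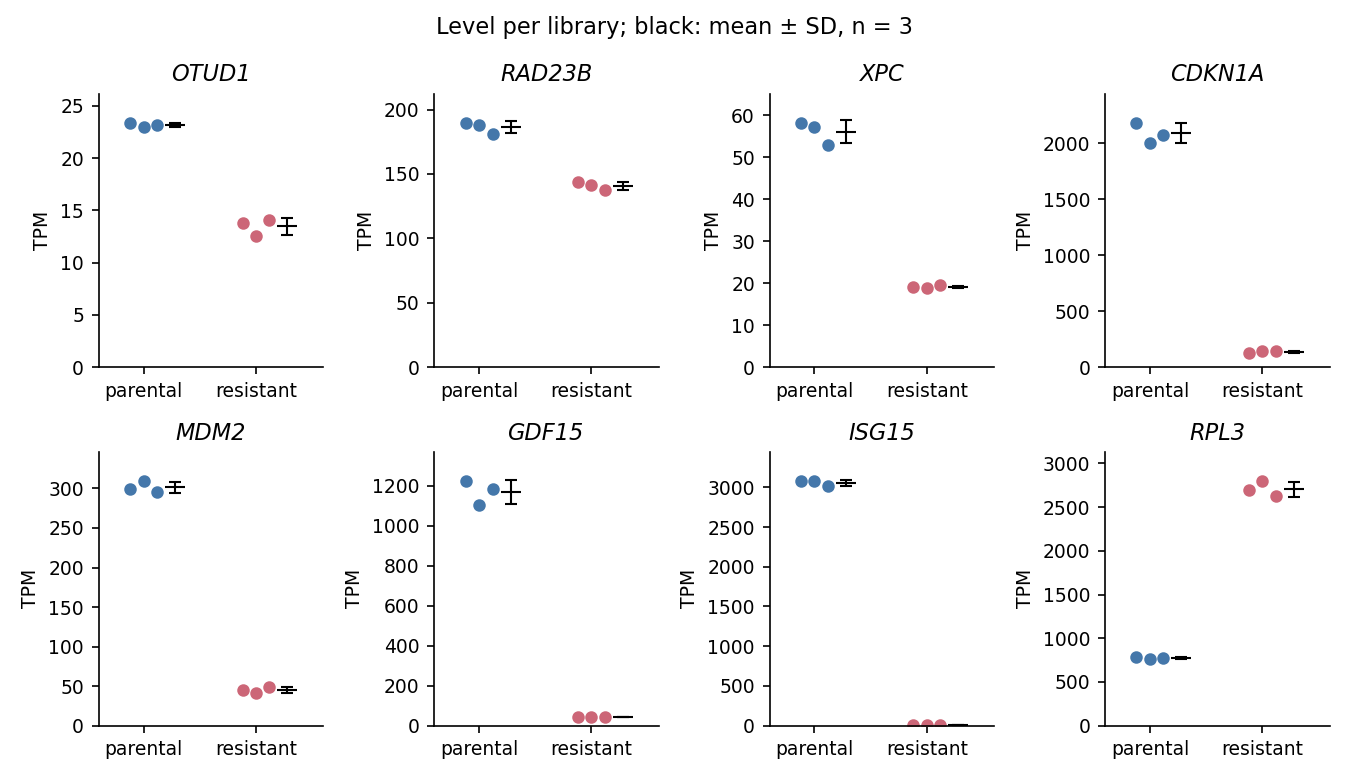
TPM (vertical axes, from 0) of OTUD1, RAD23B, XPC, CDKN1A, MDM2, GDF15, ISG15 and RPL3 in each of the 3 parental (blue) and 3 resistant (red) libraries, with the mean ± SD of each group in black. The groups do not overlap for any of the 8 genes, with RPL3 higher and the other 7 lower in the resistant libraries.

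The p53 target genes fell together. Of 30 tested members, 27 were lower, 25 of them at least 2-fold, and 1 was higher, with a median of -1.66 relative to the median gene. Adjusted over the list alone, 28 were lower and 1 was higher, and 27 were lower and 2 higher after rescaling. CDKN1A, the cyclin-dependent kinase inhibitor p21, fell from 2088 ± 89.5 to 136 ± 9.70 TPM (-3.94 ± 0.0543, adjusted p = 2.9e-12). MDM2, the ubiquitin ligase that degrades p53, fell from 301 ± 6.84 to 44.95 ± 3.48 TPM (-2.72), GDF15, a secreted stress cytokine, from 1169 ± 60.8 to 44.1 ± 0.257 TPM (-4.69), and SPATA18 from 40.00 ± 1.72 to 3.80 ± 0.189 TPM (-3.09). The list passed camera with a preset correlation (adjusted p = 9.3e-10) and not with an estimated correlation (adjusted p = 0.273 with an estimated correlation). Pro-apoptotic genes had 2 of 20 tested members higher and 14 lower (4 and 11 after rescaling), led by PMAIP1, also called NOXA and a p53 target, at -4.00, with BAX at -0.86 and BAK1 at -1.04. Anti-apoptotic genes had 3 of 11 higher and 7 lower (3 and 6 after rescaling), with BIRC3 at -3.55, CFLAR at -1.26 and BCL2L1 at -1.14. Neither of these lists passed camera (adjusted p = 0.188 and 0.303).

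Most type I interferon response genes were lower in the resistant line. Of 33 tested members, 28 were lower, 21 of them at least 2-fold, and 3 were higher (28 and 4 after rescaling), with a median of -1.44 relative to the median gene. ISG15, a ubiquitin-like protein induced by interferon, fell from 3055 ± 35.2 to 10.7 ± 0.950 TPM (-8.04 ± 0.0565, adjusted p = 2.1e-14). OASL fell from 359.8 ± 9.40 to 0.0827 ± 0.0644 TPM (-8.38), IFIT2 from 269 ± 7.20 to 2.15 ± 0.379 TPM (-6.43) and IFIT3 from 354 ± 11.6 to 4.23 ± 0.470 TPM (-6.09), and IFIT1 (-5.83) and RSAD2 (-6.44) were also among the 12 largest falls. Camera called the list (adjusted p = 3.7e-07), and the call was lost with an estimated correlation (adjusted p = 0.261 with an estimated correlation). Antigen presentation genes had 6 of 18 tested members higher and 11 lower (7 and 10 after rescaling, 7 and 11 adjusted over the list alone), with B2M, the light chain of HLA class I, at -1.18, HLA-F at -1.65 and HLA-B at -2.09. Reads of HLA class I genes can be shared between near-identical members, so the values of single HLA genes are uncertain. The NF-kappaB and cytokine list had 5 of 23 tested members higher and 17 lower, as after rescaling, including the chemokine CCL5 (-6.47) and IL1B (-3.04), whereas TNFAIP2 was higher (1.86). It missed the camera threshold (adjusted p = 0.059) and passed it after rescaling (adjusted p = 0.0114), and without rescaling it had an adjusted p of 0.579 with an estimated correlation.

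Targets of YAP/TEAD, the transcription factors of the Hippo pathway, had 16 of 21 members lower and 5 higher, as after rescaling. FJX1 fell by 2.69, GADD45A by 2.51, NT5E by 2.32 and CCN2, also called CTGF, by 2.02 on the log2 scale. GADD45A is also a p53 target. Camera called the list (adjusted p = 0.025), and not with an estimated correlation (adjusted p = 0.287 with an estimated correlation). The TGF-beta response list had 14 of 20 members lower and 5 higher (12 and 5 after rescaling), with a camera adjusted p of 0.063, which became 0.0148 after rescaling (adjusted p = 0.579 with an estimated correlation and no rescaling). The receptor gene TGFBR1 fell from 436 ± 4.40 to 47.8 ± 1.61 TPM (-3.16), and ID3 (-3.17) and PMEPA1 (-2.75) were lower as well.

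**Figure D2:**
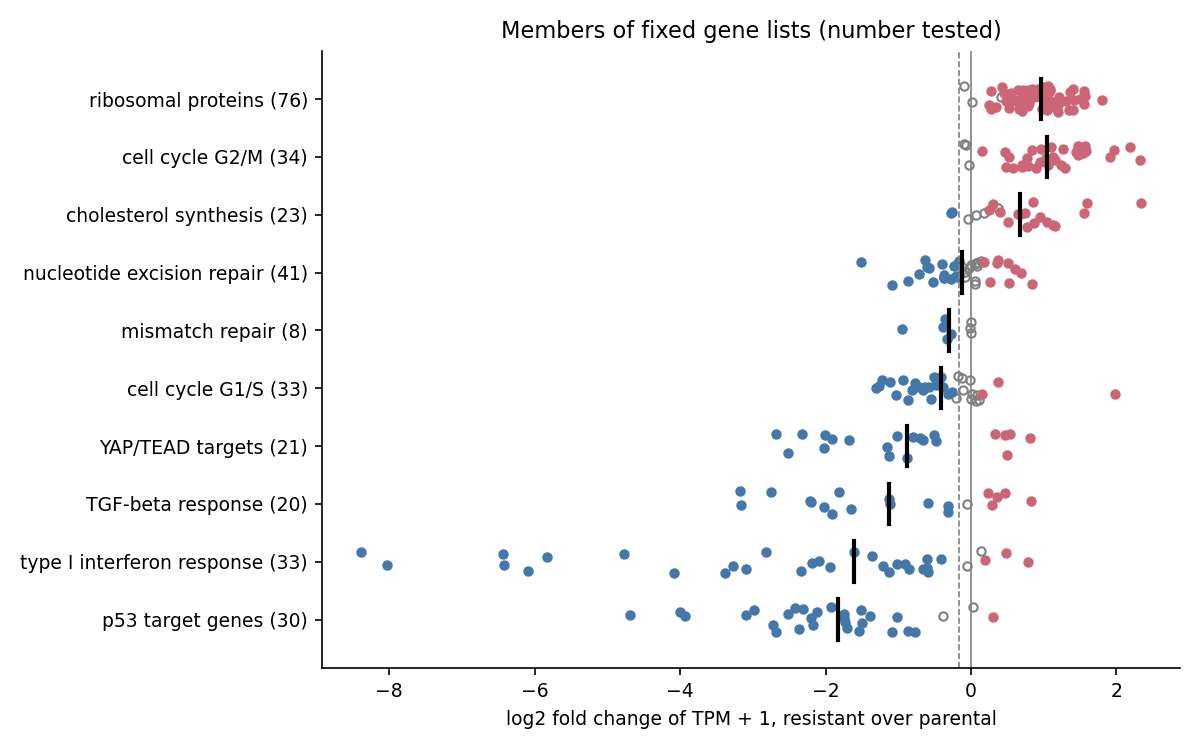
Log2 fold change of TPM + 1, resistant over parental (horizontal axis), of each tested member of 10 gene lists, with filled red points for genes called higher, filled blue points for genes called lower and open points for genes not called in limma at an adjusted p under 0.05. Black bars mark each list's median, the solid line 0 and the dashed line the median gene at -0.17; p53 targets lie lowest by median and G2/M genes highest.

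Messenger RNAs of ribosomal proteins rose nearly as a block. Of 76 tested, 73 were higher, 30 of them at least 2-fold, and 0 were lower, with a median of 1.13 relative to the median gene (75 higher and 0 lower after rescaling, 74 and 0 adjusted over the list alone). RPL3 rose from 777 ± 13.1 to 2707 ± 85.8 TPM (1.80 ± 0.0363, adjusted p = 4.0e-11), RPL5 from 372 ± 1.23 to 1108 ± 9.39 TPM (1.57) and RPL4 from 795 ± 13.2 to 2328 ± 21.6 TPM (1.55). Together these mRNAs made up 5.07 ± 0.118% of the summed TPM in the parental libraries and 10.4 ± 0.131% in the resistant libraries (SD, n = 3). The list passed camera (adjusted p = 1.1e-31; adjusted p = 0.261 with an estimated correlation). Ribosomal protein genes have many processed pseudogenes, so values of single members are uncertain where reads could be assigned to either copy. Mitochondrially encoded genes, by contrast, took 25.4 ± 0.731% and 25.04 ± 0.411% of the summed TPM, with 2 of 13 higher and 5 lower (5 and 4 after rescaling; camera adjusted p = 0.784).

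Cell cycle genes of G2/M were higher in the resistant line, whereas more genes of G1/S were lower than higher. G2/M genes had 31 of 34 higher, 18 of them at least 2-fold, and 0 lower, as after rescaling (median 1.22 relative to the median gene). AURKA, a mitotic kinase, rose from 67.00 ± 5.48 to 308 ± 3.81 TPM (2.19 ± 0.0559, adjusted p = 1.7e-10), TOP2A, a topoisomerase, from 32.4 ± 0.777 to 99.5 ± 9.005 TPM (1.58) and CCNB2, a B-type cyclin, from 6.81 ± 1.20 to 38.02 ± 2.21 TPM (2.33). Camera called this list (adjusted p = 4.5e-12), and not with an estimated correlation (adjusted p = 0.458 with an estimated correlation). G1/S genes had 3 of 33 higher and 20 lower (7 and 18 after rescaling), with CDC6 at -1.31 and DTL at -1.23, while CDT1, a replication licensing factor, was at 1.98, and the list did not pass camera (adjusted p = 0.225). Replication-dependent histone genes had 13 of 20 lower and 1 higher (12 and 1 after rescaling), with H2BC21 at -3.38 and H4C8 at -2.97, and missed the camera threshold (adjusted p = 0.073), which they passed after rescaling (adjusted p = 0.014), and had an adjusted p of 0.579 with an estimated correlation and no rescaling. Most transcripts of these genes lack a poly(A) tail, which the library preparation selects for, and their copies are near-identical, so their levels are uncertain.

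Genes of the cholesterol synthesis list were higher in the resistant line. Of 23 tested, 17 were higher and 2 lower (20 and 0 after rescaling), with a median of 0.84 relative to the median gene. INSIG1, a sterol-responsive regulator of SREBP processing, rose from 9.16 ± 1.06 to 50.1 ± 0.583 TPM (2.34), DHCR7, which catalyses the last step of cholesterol synthesis, from 58.3 ± 2.40 to 178 ± 6.32 TPM (1.59) and SREBF2, the transcription factor of the pathway, from 64.05 ± 2.002 to 144 ± 4.68 TPM (1.16). Camera gave an adjusted p of 2.9e-07, and 0.131 was the adjusted p with an estimated correlation.

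No DNA repair list passed camera. Nucleotide excision repair had 9 of 41 tested members higher and 18 lower, and 16 higher and 11 lower after rescaling, with a camera adjusted p of 0.905. Besides XPC, the lower members included DDB2 (-1.09 ± 0.0529), which also detects UV damage and is a p53 target, and PCNA (-0.86), while ERCC1, a subunit of the nuclease that makes the 5' incision, rose from 24.8 ± 1.002 to 36.00 ± 0.496 TPM (0.52). Homologous recombination and Fanconi anemia genes had 8 of 34 higher and 8 lower (11 and 6 after rescaling, 7 and 8 adjusted over the list alone), among them FANCA (0.49) and RAD51C (-0.91). Mismatch repair had 0 of 8 higher and 5 lower (0 and 3 after rescaling). Translesion synthesis had 2 of 14 higher and 8 lower (3 and 7 after rescaling), with POLH, a polymerase that can bypass cisplatin adducts and a p53 target, falling from 37.2 ± 1.90 to 12.4 ± 0.825 TPM (-1.51). The 4 lists had camera adjusted p values of 0.905, 0.514, 0.514 and 0.402.

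Transporters and detoxification genes changed in both directions. SLC31A1, the copper transporter that also carries cisplatin into cells, fell from 83.8 ± 0.136 to 63.6 ± 1.71 TPM (-0.39; -0.21 after rescaling). ATP7A, a copper-exporting ATPase, was at 5.16 ± 0.444 TPM in the parental libraries and 4.48 ± 0.434 TPM in the resistant libraries (adjusted p = 0.176), and its relative ATP7B fell by 0.47 on the log2 scale. ABCC2, an efflux pump for conjugated drugs, was at 191 ± 2.64 TPM in the parental libraries and 198 ± 6.52 TPM in the resistant libraries (adjusted p = 0.237), with a log2 fold change of 0.24 after rescaling (adjusted p = 2.3e-04). LRRC8C, a subunit of volume-regulated anion channels, fell by 1.37. Platinum uptake and export genes had 2 of 13 higher and 7 lower (2 and 6 after rescaling), and ABC efflux transporters 5 of 13 higher and 6 lower (6 and 5 after rescaling). ABCC3 (1.14) and ABCG2 (1.01) were higher and ABCB1, the multidrug pump P-glycoprotein, was lower (-2.52). NRF2 targets and glutathione genes had 15 of 34 higher and 15 lower (18 and 14 after rescaling), with TKT at 1.65 and TXNRD1 at -0.82. Of 4 metallothionein-list members tested, 1 was higher and 2 lower, as after rescaling, with MT1A, whose reads can be shared with near-identical copies, at 1.69 and MT2A at -0.72. These 4 lists did not pass camera (adjusted p = 0.53, 0.573, 0.271 and 0.867).

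The 12 largest rises included SLFN11, which acts at stressed replication forks, from 0.0968 ± 0.111 to 33.9 ± 0.781 TPM (5.0 ± 0.104, adjusted p = 5.1e-11). ITGB4, an integrin of epithelial cells, rose from 0.568 ± 0.324 to 46.5 ± 2.11 TPM (4.94), ITGA2B, the integrin of platelets, from 0.393 ± 0.156 to 32.3 ± 1.35 TPM (4.58), ALOX15 from 4.14 ± 1.06 to 76.8 ± 3.37 TPM (3.94) and the water channel AQP3 from 1.93 ± 0.324 to 31.4 ± 1.67 TPM (3.47). PXDN (4.03), CPLX2 (3.90) and HVCN1 (3.63) were also among them, as were blood-cell genes. The neutrophil proteases ELANE and PRTN3, neighbours on chromosome 19, rose from 0.937 ± 0.690 to 21.7 ± 2.19 TPM and from 0.728 ± 0.253 to 18.9 ± 3.18 TPM, NFE2 from 0.646 ± 0.361 to 20.8 ± 1.39 TPM and CD14 from 16.97 ± 1.57 to 206 ± 8.57 TPM. AZU1, in the same region and chosen after its values were seen, also rose, by 3.33 relative to the median gene. With AZU1 left out as well, the 50 other tested genes within 1 Mb of ELANE had a median of 0.26 relative to the median gene, with quartiles of -0.06 and 0.74. Of 18 leukocyte markers only CD14 and ITGAX reached the test, the latter lower (-1.50), and all 12 erythroid markers were below it. The 12 largest falls held, besides the interferon genes and CCL5, the cystatins CST2 (from 1516 ± 169.7 to 1.01 ± 0.785 TPM) and CST1 (from 27.3 ± 4.48 TPM to values listed at 0 in the 3 resistant libraries), which are near-identical paralogs and uncertain singly. GKN2 (-6.10), TCN1 (-5.46) and IGFBP1 (-5.11) completed them.

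Epithelial markers had 6 of 13 tested members higher and 4 lower (6 and 2 after rescaling), with CLDN4 at 2.54, MUC1 at 1.70 and KRT19 at -1.54. Mesenchymal markers had 11 of 22 higher and 10 lower (11 and 9 after rescaling), with COL6A1 at 2.41, VIM at 1.57 and FN1 at -0.78. Fibroblast markers had 5 of 9 higher and 4 lower (5 and 1 after rescaling), with PDGFRB at 2.38 and DCN at -1.51. The 6 squamous markers tested were lower (5 after rescaling), with SERPINB5 at -1.50 and S100A2 at -2.03. None of these lists passed camera (adjusted p = 0.303, 0.448, 0.24 and 0.063), and squamous markers did after rescaling (adjusted p = 0.028), with an adjusted p of 0.412 with an estimated correlation and no rescaling.

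By chromosome, the genes of chromosome 3 stood apart, a feature singled out after its values were seen. After removal of the trend on GC content, transcript length and expression, the 673 tested genes of this chromosome had a median log2 fold change of -0.28, with quartiles of -0.63 and 0.08. The other 22 chromosomes tested had medians from -0.06 to 0.19. Without the correction, 84 genes of chromosome 3 were called higher and 464 lower, and 119 and 399 after rescaling. XPC and TKT lie on it.

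**Figure D3:**
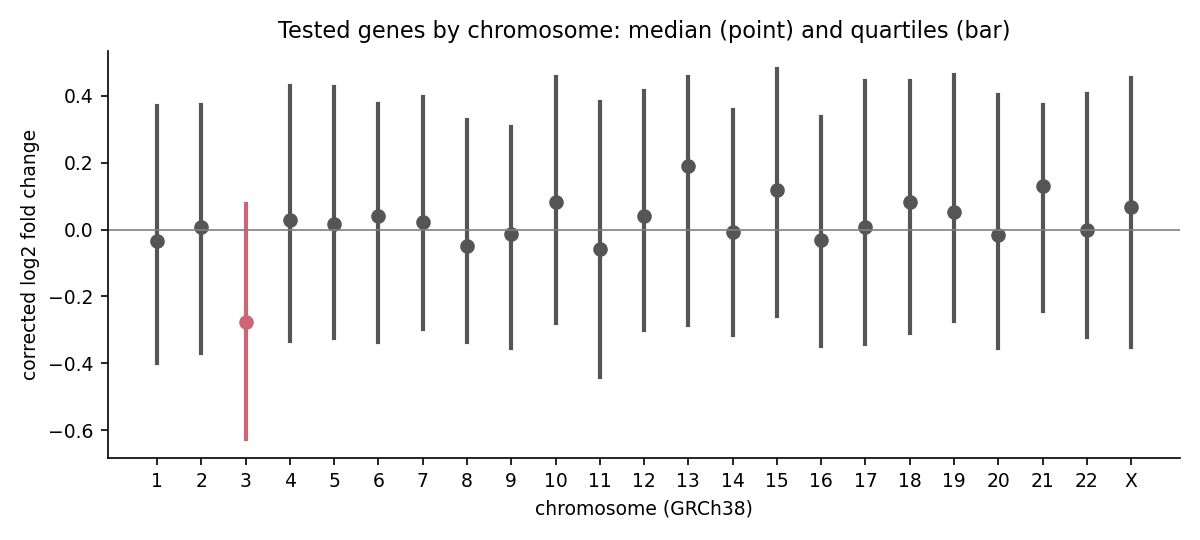
Median (point) and lower to upper quartile (bar) of the log2 fold change, resistant over parental, corrected for GC content, transcript length and expression (vertical axis), of the tested genes on chromosomes 1 to 22 and X of GRCh38 (horizontal axis). Chromosome 3, in red, has a median of -0.28, and the other medians lie between -0.06 and 0.19.

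The authors' deposited table of the same comparison lists 4398 genes as higher and 4585 as lower at an adjusted p under 0.05, of 16745 genes. Among the 12251 genes tested here, 697 were at least 2-fold higher in both and 863 at least 2-fold lower in both, out of 701 and 1063 here and 1212 and 932 in the authors' deposited table. No gene was called 2-fold in opposite directions (0 genes), and 3 were when the fold limit was left out. The 6 lists that passed camera were 6 of 36 with at least 3 tested members, and 11 had an unadjusted p under 0.05. With an estimated correlation 0 of the 36 passed, with a lowest adjusted p of 0.131 and 5 at an unadjusted p under 0.05. For lists with no count adjusted over the list alone in the text, that count equalled the one over all genes tested. The median, the mean and the camera direction differed in sign for nucleotide excision repair, homologous recombination and Fanconi anemia, ABC transporters, metallothioneins, mesenchymal markers, stemness genes, hypoxia and glycolysis and lung lineage markers, none of which passed camera.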

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

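Alternatives other than the pseudocount of 0.1, no filter, the replicate block, the left-out libraries, the estimated correlation and fry were chosen after seeing the data. The edgeR-based and count-based settings planned for raw counts (TMM, RLE, upper-quartile and total scaling, glmTreat and a DESeq2 test) were not run, since the files hold no counts. Under every alternative run, the count of genes changed stayed within 1.5 times of 8969, at 8481 to 8700 with 1 library left out and 8462 to 9631 otherwise, apart from the test against a 1.5-fold change, which called 2556. The same-numbered libraries did not deviate together (correlations 0.0097, -0.027 and 0.014), and with the replicate block 8938 genes were called, of which 3094 higher and 5728 lower genes were also called without it. Genes at least 2-fold higher numbered 1249 with limma-voom on recovered reads against 701, and the test against a 1.5-fold change, with no limit on the estimate, called 950 higher and 1606 lower genes, of which 667 and 1049 were at least 2-fold, against 701 and 1063. XPC, OTUD1 and RAD23B kept their direction and their side of the threshold in all settings, except that in the test against a 1.5-fold change OTUD1 (-0.74, adjusted p = 0.099) and RAD23B (-0.40, adjusted p = 1) did not pass. That test also ended the call of 32 of 157 other genes under the naming rule, among them FANCA, ERCC1, SLC31A1, ATP7B, TNFAIP3, OTUD6B, MAGEA1 and EGFL7. With 1 library left out XPC, OTUD1 and RAD23B ranged, in this order, from -1.55 to -1.48, -0.77 to -0.69 and -0.42 to -0.39. Camera called 6 lists, 10 with median-of-ratios and 10 with upper-quartile scaling, 6 to 8 with 1 library left out, and 0 with an estimated correlation (5 at an unadjusted p under 0.05). The replicate block changed the call of 1 list, NF-kappaB (adjusted p = 0.0486), and of no other list or named gene. That list also passed with no filter (0.0168), upper-quartile scaling (0.0076) and limma-voom (0.0042), without parental replicate 1 (adjusted p = 0.0472) or 3 (0.0432) and without resistant replicate 1 (0.0420), 2 (0.0366) or 3 (0.0345). The TGF-beta list passed with no filter (0.0242), upper-quartile scaling (0.0096) and limma-voom (0.0025), without parental replicate 1 (0.0499) or 3 (0.0432) and without resistant replicate 2 (0.0462). The histone list passed with at least 50 recovered reads (0.0065), upper-quartile scaling (0.0077) and limma-voom (0.0127) and without resistant replicate 1 (0.0381), and the squamous list with no filter (0.0111) and upper-quartile scaling (0.0253). Directional fry, which tests movement and not difference from other genes, called 30 and mixed fry 36. With fry, homologous recombination and Fanconi anemia (median -0.066, adjusted p = 0.0015) and nucleotide excision repair (-0.12, adjusted p = 5.2e-04) were down, whereas camera, against the other genes, put them up without a call. The fry difference comes from its construction, since the median gene lies at -0.17 without rescaling. The estimated correlation was 0.0048 for YAP/TEAD targets and -0.018 for cholesterol synthesis, both below the preset 0.01. A higher correlation between genes is therefore not what ended the calls of these lists. With an estimated correlation camera takes its degrees of freedom from the 6 libraries, and with a preset one from the number of genes. The estimated setting is thus the stricter test by construction, and the loss of these calls does not by itself show weaker evidence. For the other called lists the estimated correlation ran from 0.061 (type I interferon response) to 0.40 (G2/M), and these effects were not separated. Apart from this, the cause of the other changes was not tested. Under median-of-ratios scaling 1 called gene reversed its call, 9 under upper-quartile scaling and 2 under limma-voom. At these depths 62.0% of the smallest simulated changes were recovered, so small changes are the ones most often missed.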

Other observations

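Stress response genes were mostly lower in the resistant line, though none of their lists passed camera. Unfolded protein response and ATF4 targets had 9 of 27 higher and 17 lower (10 and 17 after rescaling; camera adjusted p = 0.315). ATF3, a stress-induced transcription factor, fell from 60.3 ± 4.71 to 3.14 ± 0.382 TPM (-3.89), SESN2 from 117 ± 7.34 to 21.1 ± 1.52 TPM (-2.42), also a p53 target, and STC2 from 303 ± 5.98 to 58.6 ± 3.71 TPM (-2.35), while SHMT2, an enzyme of mitochondrial one-carbon metabolism, rose from 157 ± 2.98 to 399 ± 10.3 TPM (1.34). Heat shock proteins had 4 of 17 higher and 11 lower (6 and 10 after rescaling; adjusted p = 0.292), with HSP90AA1 at -0.85 and HSPA4L at -1.22. AP-1 and immediate early genes had 5 of 22 higher and 14 lower (7 and 12 after rescaling; adjusted p = 0.255), with EGR1 at -2.82 and ETV4 at 2.10.

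Metabolic and lineage lists were mixed. Hypoxia and glycolysis genes had 10 of 28 higher and 12 lower (11 and 8 after rescaling; camera adjusted p = 0.448), with the glucose transporter SLC2A3 rising from 61.9 ± 3.16 to 326 ± 18.6 TPM (2.38) and its relative SLC2A1 falling from 184 ± 4.99 to 80.1 ± 2.49 TPM (-1.19). Stemness genes and aldehyde dehydrogenases had 5 of 13 higher and 6 lower (7 and 5 after rescaling; adjusted p = 0.548), with ALDH3A1 at -1.81, BMI1 at -1.73 and ALDH2 at 2.27. Of 5 lung lineage markers tested, 2 were higher and 1 lower, as after rescaling, the latter FOXA1 at -1.14 (camera adjusted p = 0.723). Neuroendocrine markers had 1 of 8 higher and 5 lower (3 and 4 after rescaling), with SCG2 at -1.12 (adjusted p = 0.53), and the 3 cancer-testis antigens tested had 1 higher and 2 lower, as after rescaling, with MAGEA1, a member of a family of close copies, at -0.61 (adjusted p = 0.575). The single endothelial marker tested, EGFL7, was higher (0.47).

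The tests below, apart from the splits of the 6 libraries, were chosen after the fold changes of this comparison had been seen, and the random gene sets for chromosome 3 and the bounds for the neighbours of ELANE and for the windows of neighbouring genes after the values they measure had been seen. What follows are hypotheses found and tested on the same data. Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave 8969 genes, and the highest of the others gave 0. With 10 splits a share under 0.05 cannot be reached.

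The fall of p53 targets held after correction for technical trends. After removal of the trend on GC content, length and expression the list's median was -1.68, which argues against GC content and length as the cause. Under median-of-ratios scaling the list's median was -1.66. This scaling moved genes by small amounts, the median gene from -0.17 to -0.01, and could not have undone a fall of this size. The value shows only that the fall is far larger than the difference between the scalings. A second list of p53 targets that shares no gene with the first had a median of -0.70 relative to the median gene, with 46 of 57 tested members lower and 3 higher. A candidate explanation is lower p53 activity in the resistant line, which may include the falls of XPC, DDB2 and POLH, all known p53 targets. Whether the parental cultures were under more stress was not tested and stays open.

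The rise of ribosomal protein mRNAs also held, though it was smaller after the same correction. With the trend on GC content, length and expression removed, the list's median was 0.83 (76 of 76 above 0). Genes matched to the ribosomal protein genes on length, GC content and expression (215 genes, still longer, with a median transcript of 1811 bases against 1189) had a median of 0.0553 relative to the median gene, against 1.13 for the ribosomal proteins. Under median-of-ratios scaling the list's median was 1.14. As for p53 targets, that scaling moved genes too little to undo a change of this size. Non-ribosomal mRNAs of the translation machinery that carry a 5' TOP, a sequence through which growth signals control translation and stability, had a median of 1.46 (22 of 23 above 0). The mRNAs may therefore have risen as a 5' TOP class. Differences in growth rate or medium between the cultures were not tested and stay open.

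Blood-cell genes such as ELANE, PRTN3, NFE2 and CD14 rose in a lung cancer line, and blood cells in the cultures are a technical explanation. The median over 20 abundant blood-cell genes was 0.179 TPM in the resistant libraries, 16 of the 20 lay under 1 TPM, and MPO and CTSG, made with ELANE in neutrophil precursors, were listed at 0, which argues against it. SRGN, S100A8 and S100A9, which the parental line also expresses, were the most abundant of the 20. The share of GC content or length bias cannot be told apart, since the 7 genes tested were chosen for their rise and their corrected median of 3.38 excludes nothing. Relative to the median gene, ELANE rose by 3.79, PRTN3 by 3.69 and AZU1, in the same region and chosen after its values were seen, by 3.33. A shift of the whole region would need their neighbours to rise about as far. With ELANE, PRTN3 and AZU1 left out, the 50 other tested genes within 1 Mb of ELANE had a median of 0.26 on the same scale, with quartiles of -0.06 and 0.74. The bounds first set for this median were met on neither side and were replaced after it was seen, so no verdict is drawn from bounds. The values show that most of these neighbours did not rise as far as ELANE, PRTN3 and AZU1. A smaller shift of the region stays open, and the values say nothing of NFE2 or CD14. A change limited to the stretch that holds ELANE, PRTN3 and AZU1 was not tested.

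Genes of chromosome 3 were lower as a whole, by an amount far smaller than most named changes. Of 10000 random gene sets of the same size matched on mean expression, 0 had a median as far from 0 as -0.28, a share of 0.0001, the smallest these sets can give, with random medians from -0.09 to 0.09. Compared with the other chromosomes the lower quartile differed by -0.29, the median by -0.29 and the upper quartile by -0.33, so the distribution was displaced rather than stretched. The medians of 10 consecutive bins of equal gene number along the chromosome lay between -0.39 and -0.11. A candidate explanation is fewer copies of chromosome 3 in the resistant line, or in part of its cells, which a copy number measurement could test. XPC, at -1.33 relative to the median gene without the correction, fell by more than this shift, and the 20 nearest tested genes had a corrected median of -0.17.

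On a finer scale, the medians of windows of 20 neighbouring genes were set against the largest absolute window median of each of 1000 permuted gene orders, and windows in 2 places passed the 95th percentile of these. The farthest window, at 0.81, was matched by a share of 0.0110 of the orders (10 orders, with the observed one counted in the share). A rule first set on the number of such places gave no verdict, and the share was chosen after that result was seen. The share argues against chance order of genes but does not tell why neighbours moved together. The farthest window lies within a longer stretch on chromosome 5 from 141172619 to 141682221 (GRCh38), from PCDHB7 to ARAP3. This stretch holds 33 tested genes, with a corrected median of 0.54, quartiles of 0.20 and 0.86 and 30 genes above 0. The other stretch, on chromosome 6 from 24667035 to 26378320, runs from ACOT13 to BTN3A2 with 21 tested genes and holds part of the histone cluster, and 28 orders had a window as far from 0 as its farthest (-0.76). Its genes did not shift together, with a corrected median of -0.39, quartiles of -1.55 and 0.31 and 8 genes above 0. Protocadherin and histone genes have close copies, which leaves their single values uncertain.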
